A study of Mus musculus with 15 samples.

How the data were processed

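RNA was measured in primary mouse lung fibroblasts and primary alveolar type II (ATII) cells after 24 h with vehicle or with 1 mM β-aminopropionitrile (BAPN). Per the labels' protocols, fibroblasts were passaged at least 3 times and starved for 24 h before treatment, and ATII cells were grown for 3 days at an air-liquid interface until they formed a monolayer. Per the labels' protocols, Cy3-labelled cRNA was made with an Agilent low-input kit and each sample was hybridised to an array of its own. Groups were taken from the labels: 4 vehicle and 3 BAPN arrays of fibroblasts, and 4 vehicle and 4 BAPN arrays of ATII cells. The fourth ATII BAPN array is labelled as a replacement and carries no replicate number. It entered its group by its treatment and source labels and is called BAPN replicate 5 here. The series design speaks of 4 BAPN samples, and the fibroblast BAPN sample numbered 3 was not analysed here. The labels do not say whether replicates came from separate animals or separate cultures, so p-values measure the spread between these samples, which may be technical.

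Both scanner files and a series table were used. Per the file headers, the authors' scanner files hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, background-subtracted and spatially detrended within each array but not normalized between arrays. Per the file headers the array was designed on mouse build mm9. The deposited series table holds log2 values of the same arrays. Its columns had the same sorted values to within 0.0032 and a median of 5.96 each, so the authors had quantile normalized them, and each column correlated with the log2 intensity of its own array (r of at least 0.999). These values were not centred by gene, and their direction is that of intensity. The background step and the statistical test that the authors used are not given in the sources used here.

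Each array held 62976 spots, 59305 of them for 55681 probes that are not controls. Between 65.2% and 71.2% of these spots were well above background on each array, and 0 spots were saturated. The number of arrays limits the precision. Probes were named through their accessions with a RefSeq gene table of assembly GRCm38.p6, which named 27428 probes. The symbol in the file named a further 3483 probes and an older symbol 507 probes, while 24263 probes stayed unnamed here and were kept as themselves. No coordinates were used. Spots with an outlier mark were left out and spots of a probe were averaged. This removed 469 probes that lacked a value on some array and left 132 symbols without a probe. For genes with several probes, the probe with the highest mean over all 15 arrays stood for the gene.

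The values tested were log2 processed intensity minus the array's 75th percentile over probes that are not controls, called the normalized log2 level. A feature (a gene, or an unnamed probe) was tested if it was well above background on at least 3 arrays of the groups compared. limma 3.58.1 in R 4.3.3 was fitted to all 15 arrays with a mean per group, which left 11 residual degrees of freedom, followed by empirical Bayes moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the features tested, with a threshold of 0.05. The comparisons were BAPN against vehicle in fibroblasts, the same in ATII cells, the difference between these effects (the effect in ATII cells minus that in fibroblasts), and ATII cells against fibroblasts in vehicle. Standard errors (SE) of fold changes came from this model, while standard deviations (SD) are those of the arrays of a group. Where a probe was not well above background on any array of a group, a fold is given as a bound, "at least N-fold". The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. The share of genes whose 95% interval lay inside 2-fold was counted for both BAPN effects. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

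The 30 gene lists (matrix and cross-linking genes, cell type markers, stress, metabolic and signalling pathways) were tested with limma's camera with a preset correlation between genes of 0.01, on lists with at least 3 tested members, and adjusted over the lists. Camera was repeated with an estimated correlation. Lists were adjusted over the list alone as well as over all features. Of the listed genes, Sod3, Siglec5, Hbb-b1, Gsta1 and Ccne2 had no probe under their name. The grouping, the tests, the gene lists, the alternatives planned and the rule for named genes were fixed before the data were examined. By that rule, the text names the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap. Where fewer than 10 qualified in a direction, it fills up to 10 with the genes of smallest unadjusted p in that direction. It also names every member of the lysyl oxidase family. For a list that is described, it names the members that passed, or the 2 with the largest change if more than 4 or none passed. Single members of 1 list that this rule selects are not reported here. Which lists are described was chosen after the list results were seen.

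The files place the 15 arrays on 2 slides, and the scan days split them in the same way, so the scan day was not run separately. Each slide held arrays of all 4 groups. Slide 1 held 1 fibroblast BAPN array, and slide 2 held 1 ATII BAPN array. On slide 2 every vehicle array lay in slide column 1 or 2 and every BAPN array in slide column 3 or 4, in both cell types. On slide 1 the fibroblast arrays were laid out in the same way and those of ATII cells were mixed. The alternatives set beforehand were another background correction (normexp with an offset of 50), quantile and median scaling, the deposited log2 table, other filters and probe rules, fits of the compared groups alone, other variance models, slide and replicate number as blocks, a threshold of 0.1 and leaving out each array in turn. Fits of each slide alone, of features brighter than the 75th percentile of the array, and with a correction for spot position were chosen after the data had been examined in several passes. That correction took away, within each cell type, each array's median deviation from the mean of the cell type's arrays in blocks of spots set by 12 column bins, 8 row bins and 8 intensity bins. It also removes part of any effect that BAPN has on all features of such a block. The tests on spot columns, on other probes of the same gene and on lysosomal genes were also chosen after the data had been examined. The model fixed beforehand stayed the main result throughout.

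Replicate numbers are shared between groups in the labels. For the vehicle arrays of both cell types, arrays with the same number deviated together from their group means over features (r = 0.23, 0.239, 0.309 and 0.329 for numbers 1 to 4). Odd numbers lie on slide 1 and even ones on slide 2, and for numbers 1 and 2 the correlation with another number was higher (0.293 and 0.297).

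The procedure was tested on simulated data with 200 changed features at the real spread, 67 each at 1.5-fold and 2-fold and 66 at 4-fold. Of those at 2-fold the test recovered 38.8% in the fibroblast comparison of 32255 features, 49.3% in the ATII comparison of 32045, 7.46% in the difference of effects over 34287 and 61.2% in the comparison of cell types over 32470. At a 4-fold change it recovered 78.8%, 89.4%, 57.6% and 87.9%. At a 1.5-fold change it recovered 2.99%, 16.4%, 1.49% and 11.9%. With a list shifted 1.5-fold in the simulated fibroblast comparison, camera called that list and 1 of the other lists. The simulated noise was independent between features and arrays, without effects of slide or spot position and without correlation between genes. These rates and the camera result may therefore not hold for the real arrays.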

Results

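Transcript levels were measured in primary mouse lung fibroblasts, the matrix-producing mesenchymal cells of the lung, and in primary alveolar type II (ATII) cells, the surfactant-producing epithelial cells of the alveolus. Cells received vehicle (phosphate-buffered saline) or 1 mM β-aminopropionitrile (BAPN) for 24 h. BAPN is an irreversible inhibitor of the lysyl oxidases, the copper-dependent enzymes that start the cross-linking of collagen and elastin. The question was whether BAPN alters gene expression in either cell type. Fibroblasts were represented by 4 vehicle and 3 BAPN arrays, and ATII cells by 4 vehicle and 4 BAPN arrays, each array carrying RNA of a single sample. Of 59305 non-control spots, 65.2% to 71.2% were well above background on each array, and the median coefficient of variation of replicate spots was 4.98% to 9.33%. Levels are normalized log2 intensities, so that 0 is the 75th percentile of an array.

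Vehicle-treated ATII cells and fibroblasts were compared first, to describe the identity of the cultures. Fibroblasts had been passaged and starved and ATII cells grown at an air-liquid interface, so cell type and culture conditions cannot be told apart. Cdh1, which encodes the epithelial adhesion protein E-cadherin, was at least 727-fold higher in ATII cells (level 4.35 ± 0.37 against −7.08 ± 0.105, SD, n = 4 in each group; limma with Benjamini-Hochberg adjustment, adjusted p = 3.39e-12). The secreted protein gene Wfdc2 was at least 1015-fold higher (4.83 ± 0.69 against −7.15 ± 0.26, adjusted p = 9.3e-11), and the lung epithelial transcription factor gene Foxa1 at least 208-fold (adjusted p = 1.08e-10). Epcam, which encodes an epithelial adhesion molecule, was 722-fold higher (log2 change 9.50 ± 0.45, SE) and was above background on 1 of 4 fibroblast arrays. In the other direction, Ccn5, a matricellular gene of mesenchymal cells, was 299.8-fold lower in ATII cells (log2 change −8.23 ± 0.22, SE; −2.75 ± 0.36 against 5.48 ± 0.37, SD, n = 4 in each group; adjusted p = 4.12e-11). The complement gene C1qc was 152-fold lower, with a level of 0.97 ± 0.74 in fibroblasts and 1 of 4 ATII arrays above background.

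The other large rises were in Mab21l4 (at least 604-fold), Mal2 (at least 421-fold), Tspan1 (at least 521-fold), Ctse (at least 209-fold), the growth factor gene Fgf21 (at least 142-fold) and the cytokine gene Csf2 (at least 135-fold). The other large falls were in Alkal1 (199-fold), Clca3a1 (176-fold), the pentraxin gene Ptx3 (171-fold), Clca3a2 (159-fold), Lce1g (117-fold, above background on 1 of 4 ATII arrays), Prl2c5 (93.6-fold), Ms4a7 (at least 84.6-fold) and Serpina3n (at least 34.6-fold). In all, 10081 of 32470 features passed, 4676 higher and 5405 lower in ATII cells, and 7026 of them carried a gene symbol. With slide as a block the count was 10144, and the arrays of slide 1 and slide 2 alone gave 6598 and 4626 with fewer samples. The median over all features was −0.13, and quantile scaling and the deposited table shifted it by 0.11, so changes of this size depend on the scaling.

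Epithelial genes rose together in ATII cells. Of 26 tested junction and keratin genes, 25 were higher and 0 lower (26 higher when adjusted over the list alone), with a median log2 change of 5.34 (camera with Benjamini-Hochberg, adjusted p = 4.82e-27; adjusted p = 0.044 with an estimated correlation). The median was 4.82 with the 4 members below background in fibroblasts set to their bound, and 5.59 and 4.98 on slides 1 and 2. Of 19 ATII markers, 13 were higher and 3 lower (the same counts adjusted over the list alone), with a median of 1.67, or 1.39 with bounds (adjusted p = 1.42e-06; adjusted p = 0.0322 with an estimated correlation). Sftpc, which encodes surfactant protein C, was at least 78.3-fold higher (adjusted p = 5.22e-08), and Nkx2-1, a transcription factor gene of lung epithelium, at least 12.8-fold (adjusted p = 2.35e-11). The members of this list that were lower, chosen after their values were seen, were the lysozyme genes Lyz1 (log2 change −3.31) and Lyz2 (−4.20, also a macrophage marker) and the growth factor receptor gene Fgfr2 (−0.83). The slide 1 and slide 2 medians were 1.51 and 1.25, and the 7 bright members alone had a median of 0.16 and did not pass (adjusted p = 0.699).

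Markers of other epithelial cells were also higher. Among 16 markers of alveolar type I cells, the flat gas-exchange cells, 8 were higher and 3 lower (9 and 4 adjusted over the list alone; median 1.24, adjusted p = 0.0425, and adjusted p = 0.252 with an estimated correlation). The keratin gene Krt7 rose 361-fold (log2 change 8.50 ± 0.87, SE), whereas Igfbp2 fell 92.9-fold (−6.54 ± 0.27). Krt7 and Krt19 are also members of the junction and keratin list, so the results of these lists share genes. The type I list missed the threshold after quantile scaling (adjusted p = 0.0915) and after the position correction (adjusted p = 0.0616), and its 12 bright members had a median of 0.26 (adjusted p = 0.696). Among 13 club, ciliated and basal airway markers, 8 were higher and 0 lower (8 and 3 adjusted over the list alone; median 1.22, adjusted p = 0.00265, and adjusted p = 0.314 with an estimated correlation). Foxj1, the regulator of motile cilia, was at least 25.5-fold higher and the secretory gene Bpifa1 at least 5.01-fold. Medians on slides 1 and 2 were 1.05 and 1.02 for type I markers and 1.43 and 1.06 for airway markers.

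Fibroblast and leukocyte markers were lower in ATII cells. Of 25 fibroblast markers, 14 were lower and 2 higher (15 and 2 adjusted over the list alone; median −0.69, adjusted p = 0.000384, and adjusted p = 0.252 with an estimated correlation). Fgf10, a mesenchymal growth factor gene, fell 37.3-fold (log2 change −5.22 ± 0.44, SE), and the homeobox gene Meox1 rose 32.8-fold (5.04 ± 0.59). The medians on slides 1 and 2 were −0.77 and −0.58, and on slide 2 alone the list did not pass (adjusted p = 0.0569). Of 20 macrophage and leukocyte markers, 14 were lower and 3 higher (the same adjusted over the list alone; median −1.65, adjusted p = 0.00044, and adjusted p = 0.314 with an estimated correlation; −1.46 and −1.84 on slides 1 and 2). The neutrophil and monocyte gene S100a8 was at least 28.9-fold lower, and Tyrobp, which encodes a myeloid signalling adaptor, fell 19.1-fold (−4.26 ± 0.47).

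Metabolic and stress genes differed as well, and culture conditions cannot be told apart from cell type here either. Cholesterol synthesis and SREBP target genes were higher in 19 of 20 tested members (19 adjusted over the list alone; median 1.35, adjusted p = 2.4e-17, and adjusted p = 0.0322 with an estimated correlation; 1.31 and 1.37 on slides 1 and 2). Hmgcs1, an enzyme gene of this pathway, rose 4.12-fold (log2 change 2.04 ± 0.12, SE). Of 24 integrated stress response and amino acid genes, 16 were higher and 1 lower (the same adjusted over the list alone; median 1.07, adjusted p = 1.67e-08, and adjusted p = 0.272 with an estimated correlation; 0.98 and 1.16 on slides 1 and 2), with Fgf21 and the amino acid transporter gene Slc7a3 (13.1-fold) changing most. Of 20 unfolded protein response genes, 8 were higher and 0 lower (10 higher adjusted over the list alone; median 0.31, adjusted p = 0.000103, and adjusted p = 0.183 with an estimated correlation; 0.29 and 0.35 on slides 1 and 2). Herpud1 rose 1.99-fold and the chaperone gene Hspa5 1.75-fold. Of 21 NRF2 and glutathione genes, 10 were lower and 2 higher (11 and 2 adjusted over the list alone; median −0.60, adjusted p = 0.00384, and adjusted p = 0.325 with an estimated correlation; −0.65 and −0.78 on slides 1 and 2), with the quinone reductase gene Nqo1 down 13.1-fold and the glutathione peroxidase gene Gpx2 up 77.4-fold.

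**Figure D1:**
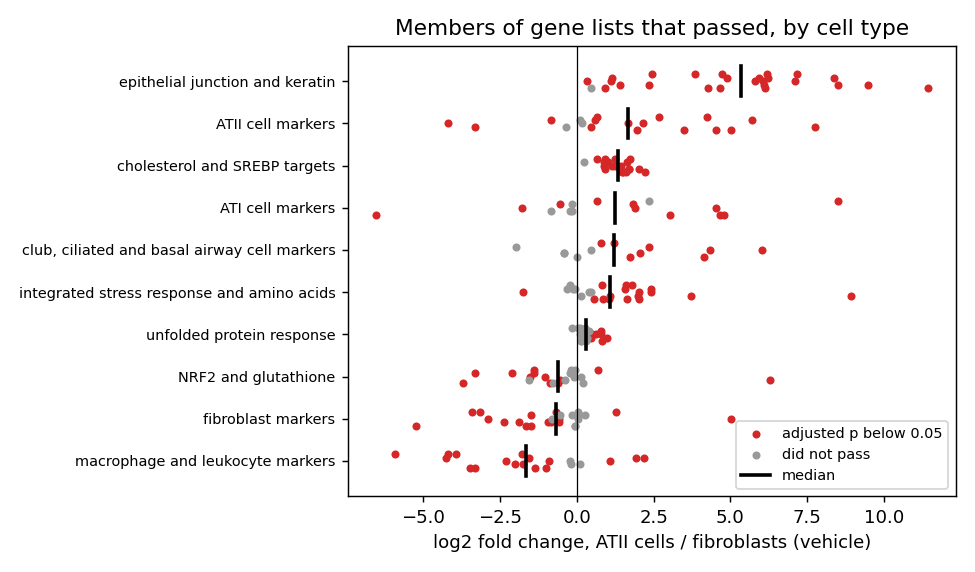
Log2 fold change of ATII cells over fibroblasts, both in vehicle (n = 4 each), on the horizontal axis for the tested members of the 10 gene lists that passed. Each point is a gene, red with an adjusted p below 0.05 and grey otherwise, and a black bar marks the list median, which runs from −1.65 for macrophage and leukocyte markers to 5.34 for epithelial junction and keratin genes.

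Lysyl oxidase genes were expressed in both cell types at different levels. Loxl2 was 3.12-fold higher in ATII cells (log2 change 1.64 ± 0.38, SE; adjusted p = 0.00422), whereas Loxl3 was 3.58-fold lower (−1.84 ± 0.11; adjusted p = 6.4e-08), Loxl4 1.90-fold lower (−0.93 ± 0.20; adjusted p = 0.00314) and Loxl1 1.35-fold lower (−0.43 ± 0.15; adjusted p = 0.0388). Lox itself had a log2 change of −0.34 ± 0.15 that did not pass (adjusted p = 0.118). Loxl1 lost its call in several alternatives, Loxl2 on slide 2 alone and Loxl4 on slide 1 alone. Across the family 1 member was higher and 3 lower (1 and 4 adjusted over the list alone), and the list did not pass (median −0.43, adjusted p = 0.191). Of 16 fibrillar and other collagens, 2 were higher and 5 lower (the same adjusted over the list alone; median 0.01, adjusted p = 0.931), with Col5a3 up 14.6-fold and Col14a1 down 4.43-fold.

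With slide as a block, each of the 10 lists that passed stayed past the threshold (adjusted p from 3.69e-27 to 0.0279), and 3 of them held with an estimated correlation. The other 20 lists had adjusted p from 0.109 to 0.979. The median, the mean and the direction of the test differed in sign for basement membrane, collagen modification, matrix protease, p53 and inflammation genes.

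BAPN was next compared with vehicle in fibroblasts. Among transcripts well above background, Rad51c, a DNA repair gene, rose 2.75-fold (log2 change 1.46 ± 0.36, SE; 4.95 ± 1.09, SD, n = 3 against 3.49 ± 0.30, n = 4; limma with Benjamini-Hochberg adjustment, adjusted p = 0.022). The histone methyltransferase gene Suv39h2 rose 2.51-fold (1.33 ± 0.37; adjusted p = 0.033), and the transcription factor gene Gcm1 2.49-fold (1.32 ± 0.35; adjusted p = 0.0281). The protein disulfide isomerase genes Pdia3, Pdia4 and Pdia6, which help proteins fold in the endoplasmic reticulum, rose 1.39-fold, 1.48-fold and 1.44-fold. The largest falls were in dim transcripts, such as the lipase-related gene Pnliprp1 (at least 2.35-fold; −7.32 ± 0.19, n = 3 against −4.49 ± 0.47, n = 4; adjusted p = 0.000807) and the T cell co-receptor gene Cd8a (8.63-fold; −5.32 ± 0.92 against −2.21 ± 0.53; adjusted p = 0.0111; above background on 1 of 3 BAPN arrays). The lysyl oxidase family, the target of BAPN, had 0 of 5 members past the threshold.

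In all, 4193 of 32255 features passed, 746 higher and 3447 lower with BAPN, and 1769 of them carried a gene symbol. The other large rises were in Mak (6.25-fold) and Defb45 (3.48-fold), each above background on 2 of 4 vehicle arrays, and in Atp6v1g3 (2.53-fold), Olfr76 (at least 2.23-fold), Olfr1294 (at least 1.83-fold), Themis (at least 1.22-fold) and Tmem132e (at least 1.13-fold). The other large falls were in Ugt2b37 (8.74-fold) and Pdx1 (6.25-fold), each above background on 1 of 3 BAPN arrays, so that these folds are uncertain, and in Exph5 (at least 4.83-fold), Fam170a (at least 4.04-fold), 4921513I03Rik (at least 3.61-fold), Ahsg (at least 3.45-fold), Oaz3 (at least 2.95-fold) and Svs5 (at least 2.90-fold). Of the 4193 features, 3975 had their spot in columns above 82 of the 164 columns of the array, where 50.2% of tested features lay. On slide 2 the log2 change was −4.32 for Ugt2b37 and −3.80 for Pdx1, and on slide 1 it was −0.88 and −0.48. In contrast, 4921513I03Rik, Ahsg and Pnliprp1 had more similar values on both slides. None of them was well above background on any BAPN array, so the size of these values is uncertain. Rad51c and Suv39h2 had larger values on slide 1, with its 1 BAPN array (2.43 and 2.52), than on slide 2 (1.10 and 0.81), and neither passed after the position correction (adjusted p = 0.0827 and 0.0886), whereas 4 of the 10 rises named, Defb45, Themis, Atp6v1g3 and Tmem132e, had larger values on slide 2. After a correction for spot position 1727 features passed, among them Pnliprp1, Cd8a, Exph5, Pdx1, Oaz3 and Atp6v1g3 of the genes named with the largest changes.

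The count differed between slides, with 304 features on slide 1, which held 1 BAPN array, 6964 on slide 2, and 4341 with slide as a block. It was 815 without BAPN replicate 2, 1609 without BAPN replicate 4, 1608 without vehicle replicate 2 and 1828 without vehicle replicate 4. Fitting fibroblast arrays alone gave 2016, and features brighter than the 75th percentile gave 1060. With the replicate number as a block, an alternative set beforehand, the count was 0. The balance of directions changed too, with 240 higher and 64 lower on slide 1, 771 and 289 among bright features, 2636 and 4328 on slide 2, 498 and 1229 after the position correction, and 42 and 1974 with fibroblast arrays alone. The 95% interval of the BAPN effect lay inside 2-fold for 60.5% of tested features.

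**Figure D2:**
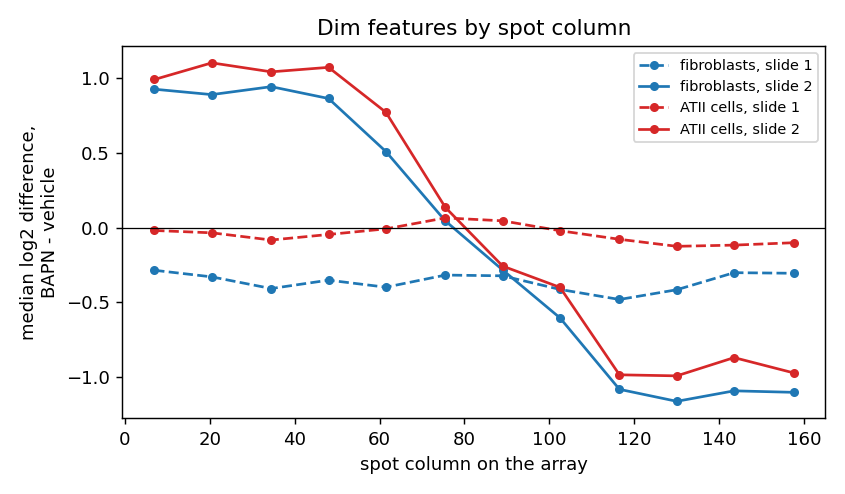
Median log2 difference between BAPN and vehicle arrays (vertical axis) of dim features in 12 bins of spot columns (horizontal axis), for fibroblasts in blue and ATII cells in red, on slide 1 (dashed) and slide 2 (solid). On slide 2 the median ran from 0.92 to −1.10 across the columns in fibroblasts and from 0.99 to −0.97 in ATII cells, while on slide 1 it stayed between −0.48 and −0.29 in fibroblasts and between −0.13 and 0.06 in ATII cells.

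With no block for slide or replicate number, individual lysyl oxidase genes differed from vehicle by less than the spread allows to call. The level of Loxl1 differed between slides, and within each slide it was lower on every BAPN array than on every vehicle array. It was 5.56 with BAPN against 5.67 and 5.73 on slide 1, and 5.73 and 5.74 against 6.17 and 6.27 on slide 2. Loxl3 was higher with BAPN on each slide, and for Lox, Loxl2 and Loxl4 the groups overlapped on slide 2. The log2 changes were 0.04 ± 0.17 for Lox (SE; adjusted p = 0.9), −0.28 ± 0.16 for Loxl1 (adjusted p = 0.287), −0.18 ± 0.41 for Loxl2 (adjusted p = 0.817), 0.23 ± 0.12 for Loxl3 (adjusted p = 0.258) and −0.15 ± 0.22 for Loxl4 (adjusted p = 0.699). As a list they had a median of −0.15 (camera, adjusted p = 0.983; 0 adjusted over the list alone). The value of Lox changed sign under quantile scaling (−0.056).

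**Figure D3:**
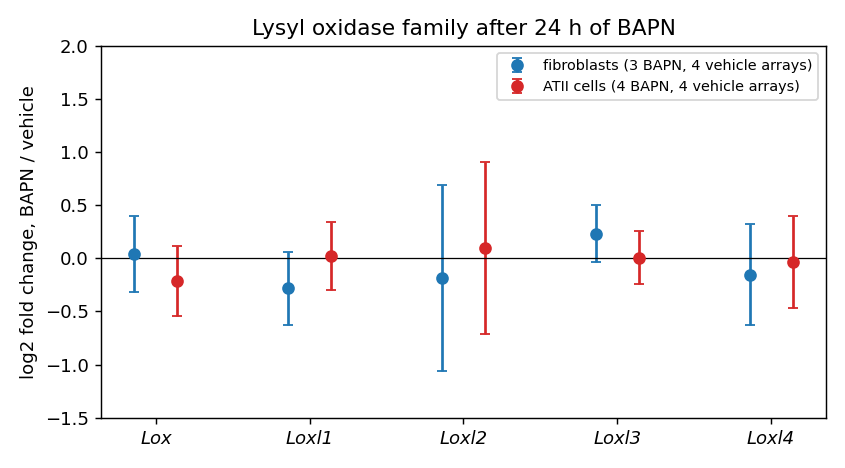
Log2 fold change of BAPN over vehicle (vertical axis) for the 5 lysyl oxidase genes (horizontal axis) in fibroblasts (blue, 3 BAPN and 4 vehicle arrays) and ATII cells (red, 4 and 4 arrays). Points are the estimates and bars their 95% intervals, from the model with no block for slide or replicate number, and each interval spans 0.

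Of the 30 gene lists, cell cycle and unfolded protein response genes passed in fibroblasts. Cell cycle genes had a median log2 change of 0.29, with 22 of 26 above 0 and 0 past the threshold singly (0 adjusted over the list alone; camera, adjusted p = 0.00206, and adjusted p = 0.991 with an estimated correlation). The mitotic kinase gene Cdk1 had a log2 change of 0.53 ± 0.20 (SE; adjusted p = 0.1) and the proliferation marker Mki67 0.44 ± 0.18 (adjusted p = 0.135). Unfolded protein response genes had a median of 0.23, with 17 of 20 above 0 and 3 higher, the isomerases named above (5 adjusted over the list alone; adjusted p = 0.00237, and adjusted p = 0.991 with an estimated correlation). The changes were 0.48 ± 0.15 for Pdia3 (adjusted p = 0.0499), 0.56 ± 0.13 for Pdia4 (adjusted p = 0.0201) and 0.53 ± 0.16 for Pdia6 (adjusted p = 0.0456), and after the position correction the adjusted p was 0.321, 0.165 and 0.208. Medians on slides 1 and 2 were 0.42 and 0.16 for cell cycle and 0.34 and 0.21 for unfolded protein response genes. Both lists passed with slide as a block (adjusted p = 0.00238 for each) and on slide 1, but not on slide 2 alone (0.952 for each), after the position correction (0.0674 for each) or after quantile scaling (0.159 and 0.162). Without BAPN replicate 1 the adjusted p was 0.0212 for cell cycle and 0.0897 for unfolded protein response genes, and 1 list passed without vehicle replicate 3.

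Matrix genes did not move as lists. Of 16 fibrillar and other collagens 1 fell, Col15a1, by 1.14 ± 0.30 on the log2 scale (adjusted p = 0.0281; −0.47 and adjusted p = 0.413 after the position correction; 1 adjusted over the list alone; list median 0.08, adjusted p = 0.631). Of 16 elastic fibre genes 0 passed (0 adjusted over the list alone; median 0.10, adjusted p = 0.631), and the fibrillin gene Fbn2 (0.96 ± 0.40) and Mfap5 (0.31 ± 0.25) had the largest values. Of 21 TGF-beta pathway genes 1 rose, the receptor gene Tgfbr1, by 1.31-fold (0.39 ± 0.10; adjusted p = 0.0249; 1 adjusted over the list alone; list median 0.10, adjusted p = 0.239). After the position correction Tgfbr1 had 0.19 (adjusted p = 0.282), and its 1 other probe went the other way. The 28 lists that did not pass had adjusted p from 0.239 to 0.983, and marker lists of other cell types were among them. The median, the mean and the direction of the test differed in sign for basement membrane, ATII marker, mesothelial, red cell, inflammation and immediate early genes.

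In ATII cells, limma with Benjamini-Hochberg adjustment called 0 of 32045 features between BAPN and vehicle. An unadjusted p under 0.05 was found for 3230 features (10.1%), and the smallest adjusted p was 0.271. The gene with that value, Uap1l1, had a 2.61-fold higher mean with BAPN (log2 change 1.39 ± 0.205, SE; 2.47 ± 0.38 against 1.08 ± 0.35, SD, n = 4 in each group). Next were Vat1 (1.57-fold; 0.65 ± 0.10; adjusted p = 0.316) and Renbp, which encodes a renin-binding epimerase (2.06-fold; 1.04 ± 0.17; adjusted p = 0.35). The 5 lysyl oxidase genes had log2 changes between −0.22 and 0.10. The 95% interval lay inside 2-fold for 69.7% of tested features.

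The other genes of smallest unadjusted p with higher values under BAPN, each with an adjusted p of 0.475, were the proton pump gene Atp6v0a1 (1.58-fold), Itgbl1 (2.32-fold), the growth factor gene Vegfb (1.59-fold), the lysosomal peptidase gene Dpp7 (2.05-fold), the lysosomal sialidase gene Neu1 (1.47-fold), Lrrc27 (1.56-fold) and the fatty acid binding protein gene Fabp3 (2.26-fold). Those with lower values, also at 0.475, were Brca1 (at least 1.49-fold), Nanos1 (1.42-fold), Epx (at least 1.26-fold), Gm6340 (1.64-fold), Srprb (1.37-fold), Lrr1 (1.42-fold), Cep78 (1.29-fold), Platr10 (1.95-fold, above background on 1 of 4 BAPN arrays), the chemokine gene Ccl24 (2.14-fold) and Ear10 (1.41-fold). The slide 1 and slide 2 values were 1.31 and 1.80 for Uap1l1, 0.62 and 0.81 for Vat1, and 1.01 and 1.26 for Renbp. Other settings called 2 features (intensity trend and robust moderation), 3 (bright features alone), 14 (array weights) and 5266 (slide 2 alone, with 1 BAPN array), whereas slide 1 alone, slide as a block and the position correction called 0.

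Single lysyl oxidase genes had log2 changes of −0.22 ± 0.15 for Lox (SE; adjusted p = 0.531), 0.02 ± 0.15 for Loxl1 (adjusted p = 0.959), 0.10 ± 0.38 for Loxl2 (adjusted p = 0.935), 0.01 ± 0.11 for Loxl3 (adjusted p = 0.987) and −0.03 ± 0.20 for Loxl4 (adjusted p = 0.959). Quantile scaling turned the sign of Loxl1 (−0.0077) and median centring that of Loxl3 (−0.0018). The list had an adjusted p of 0.919 by camera (0 adjusted over the list alone).

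Of the 30 lists 0 passed in ATII cells by camera, with adjusted p from 0.158 to 0.998 and 0.998 for every list with an estimated correlation. Before adjustment, 5 lists had a p under 0.05. Hypoxia and glycolysis genes came first (median log2 change −0.09, 4 of 21 above 0, adjusted p = 0.158), with Pdk1, an inhibitor of mitochondrial pyruvate use, at −0.65 ± 0.20 and Bnip3, a mitochondrial turnover gene, at −0.49 ± 0.20 (SE). Cholesterol genes had a median of 0.11 (15 of 20 above 0, adjusted p = 0.171), with Lss at 0.33 ± 0.17. Amine oxidase and copper handling genes had a median of 0.13 (9 of 12 above 0, adjusted p = 0.171), led by the metallothionein genes Mt1 (0.75 ± 0.18, 1.68-fold) and Mt2 (0.54 ± 0.17, 1.46-fold), which bind copper and zinc. These 2 were higher when adjusted over the list alone, and neither passed over all features (adjusted p = 0.475). Unfolded protein response genes had a median of −0.10 (4 of 20 above 0, adjusted p = 0.171), with Edem1 at −0.42 and Pdia3 at −0.24, and cell cycle genes a median of −0.11 (7 of 26 above 0, adjusted p = 0.202). Adjusted over the list alone, 0 genes passed in the hypoxia, cholesterol, unfolded protein response and cell cycle lists.

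ATII markers had a median of 0.12 with BAPN (13 of 20 above 0, adjusted p = 0.919, 0 adjusted over the list alone), with the alarmin gene Il33 at −0.51 ± 0.38 and the invariant chain gene Cd74 at 0.32 ± 0.38. Macrophage and leukocyte markers had a median of −0.06 (adjusted p = 0.919). The median, the mean and the direction of the test differed in sign for lysyl oxidase, basement membrane, epithelial, endothelial, p53 and inflammation genes. The number of lists past the threshold was 3 without BAPN replicate 4, and 1 on slide 1 alone and without vehicle replicate 1, 2 or 3 or BAPN replicate 1.

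Whether the BAPN effect differed between the cell types was tested as the effect in ATII cells minus that in fibroblasts. Single genes did not pass: limma with Benjamini-Hochberg adjustment called 0 of 34287 features, with 4731 (13.8%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0592. That value belonged to Pnliprp1, the lipase-related gene that fell in fibroblasts. No size is given for it, since it was above background on 0 of 3 fibroblast BAPN arrays. Unfolded protein response and cell cycle genes had lower effects in ATII cells than in fibroblasts as lists with the preset correlation (adjusted p = 1.47e-06 and 1.04e-06), but not with an estimated one (0.24 and 0.943). The differences of single lysyl oxidase genes lay between −0.26 and 0.30.

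Cell cycle genes had a median difference of −0.38, with 2 of 26 above 0 (0 adjusted over the list alone; camera, adjusted p = 1.04e-06, and adjusted p = 0.943 with an estimated correlation). Cdk1 had a difference of −0.64 ± 0.27 (SE; adjusted p = 0.319) and Mki67 −0.60 ± 0.24 (adjusted p = 0.304). The median was −0.44 on slide 1 and −0.37 on slide 2 (adjusted p = 0.000217 and 0.000403). Unfolded protein response genes had a median difference of −0.32, with 2 of 20 above 0 (4 lower adjusted over the list alone; adjusted p = 1.47e-06, and adjusted p = 0.24 with an estimated correlation). Edem1, which marks misfolded proteins for removal, had −0.93 ± 0.23 (adjusted p = 0.184) and Pdia3 −0.72 ± 0.20 (adjusted p = 0.196). The median was −0.34 on slide 1 and −0.24 on slide 2 (adjusted p = 2.06e-05 and 0.00137). With slide as a block the adjusted p was 8e-06 for cell cycle and 2.6e-06 for unfolded protein response genes.

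TGF-beta pathway genes had a median difference of −0.18, with 4 of 21 above 0 (0 adjusted over the list alone; camera, adjusted p = 0.0214, and adjusted p = 0.865 with an estimated correlation), with Tgfbi at −0.68 and the co-receptor gene Tgfbr3 at −0.56. Fibroblast markers had a median difference of −0.25, with 8 of 25 above 0 (0 adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.943 with an estimated correlation), with Cdh2, the N-cadherin gene, at −0.73 and Tcf21, a mesenchymal transcription factor gene, at −0.63. Both calls ended with slide as a block (adjusted p = 0.081 and 0.184), though the medians stayed about as large (−0.175 and −0.20). They also ended on slide 2 alone (0.555 and 0.584), without fibroblast BAPN replicate 1 (0.0743 and 0.304) and after the position correction (0.618 for each). Slide medians were −0.22 and −0.09 for TGF-beta and −0.23 and −0.17 for fibroblast genes on slides 1 and 2. The number of lists was also 2 without fibroblast vehicle replicate 1, ATII vehicle replicate 2 or 4, or ATII BAPN replicate 1.

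The genes of smallest unadjusted p after Pnliprp1, each with an adjusted p of 0.184, had higher effects in ATII cells for Mia (2.03-fold), Zyg11b (1.79-fold), Dynlrb2 (3.18-fold), Dact2 (2.86-fold), Amer3 (5.21-fold), Tmem178b (3.17-fold), Vat1 (1.76-fold), the epithelial transcription factor gene Ehf (3.46-fold) and Tm6sf2 (2.17-fold). They had lower effects there for the centromere gene Mis18a (1.81-fold), the DNA repair gene Brca1 (no size given, above background on 0 of 4 ATII BAPN arrays), Psmd14 (1.81-fold), Dbf4 (1.78-fold), Dhx15 (1.82-fold), Zbtb38 (1.84-fold), Gjc1 (2.34-fold), Lrrc40 (2.31-fold), Socs6 (1.80-fold) and the histone mRNA gene Slbp (2.08-fold). The lysyl oxidase differences were −0.26 for Lox (adjusted p = 0.644), 0.30 for Loxl1 (0.554), 0.28 for Loxl2 (0.874), −0.22 for Loxl3 (0.581) and 0.12 for Loxl4 (0.905), and the list had an adjusted p of 0.909. The count of genes was 1930 with array weights, 271 without ATII BAPN replicate 4, 142 among bright features, 92 on slide 1 alone, 15 without fibroblast BAPN replicate 1, 1 without fibroblast vehicle replicate 1 or BAPN replicate 2, and 2 with normexp or with no filter. It was 0 with slide as a block, on slide 2 alone and after the position correction. The 26 lists that did not pass had adjusted p from 0.213 to 0.921. The median, the mean and the direction of the test differed in sign for lysyl oxidase, amine oxidase, mesothelial, inflammation and cholesterol genes.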

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

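The tests on spot columns, on other probes of the same gene, on single slides and with the position correction were chosen after the results were seen, and so was the way lost list calls are read here, whereas leaving out arrays and the counts over other splits of the arrays were planned.

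Of the fibroblast features past the threshold, 94.8% had their spot in the upper range of columns, a test that could have given about 50.2%, so the position of the spot on the array is a candidate explanation for most of these calls. On slide 2, where vehicle and BAPN arrays lay in different slide columns in both cell types, the differences between BAPN and vehicle correlated between fibroblasts and ATII cells across 34287 features (r = 0.75, features are not independent replicates). On slide 1 they hardly did (r = 0.0388). Fibroblast arrays were laid out in the same way on slide 1, but their medians of dim features stayed between −0.48 and −0.29 over the spot columns. Of 568 other detected probes of the genes past the threshold, 20.6% went the same way at an unadjusted p under 0.05 (63.2% at any p). In the comparison of cell types, 65.3% (85.7% at any p) of 2790 such probes did. The probe that stood for a gene was its brightest, and brightness and effect size were not matched between the comparisons. These shares therefore do not settle whether an effect of BAPN on the transcripts is the whole cause. Of the 35 splits of the 7 fibroblast arrays, 1, the real one, gave as many genes (4193; highest other 193), so chance can be excluded over these splits, but not the slide position that goes with the treatment, and the 18 splits that keep the numbers of arrays on each slide are too few for a share under 0.05. An effect of BAPN on part of these genes stays open, since 1727 features passed after the position correction.

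The list call for cell cycle genes with BAPN in fibroblasts was lost with an estimated correlation, which leaves the median as it is (adjusted p = 0.991, as for unfolded protein response genes). It was also lost with the position correction (adjusted p = 0.0674), where the list median went from 0.29 (SD 0.17 over genes) to 0.16 (SD 0.13). As that correction also works within intensity bins, spot position or brightness may account for the loss, and these were not tested apart. Without fibroblast BAPN replicate 1, an array whose level relative to vehicle went from −0.29 among the dimmest 25% of features to 0.15 among the brightest, the median was 0.27 and the adjusted p 0.0212, which argues against that array as the whole cause, although on slide 2 alone, with fewer arrays, the median was 0.16 and the adjusted p 0.952. For unfolded protein response genes the call was lost without that array (adjusted p = 0.0897; median from 0.23, SD 0.21, to 0.20, SD 0.22) and with the position correction (0.0674; to 0.22, SD 0.17, and Pdia4 from 0.56 to 0.30), but as the median kept most of its size and why the call ended was not tested, both explanations stay open. Both lists lay above the median of all features on each slide, by at least 0.156 for cell cycle and at least 0.202 for unfolded protein response genes. An effect of BAPN would also give this, but it cannot decide, since the lists were picked as higher in these same arrays. Among bright features, whose median was 0.08, the list medians were 0.29 over 24 members and 0.24 over 18 (camera, adjusted p = 0.0619 and 0.0497). Of the 35 splits of the fibroblast arrays, 27 gave at least the 2 lists of the real split (highest other 12), so chance cannot be excluded.

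The effects of BAPN in the cell types differed for 4 lists by the test of the difference itself, with adjusted p of 1.04e-06 for cell cycle genes, 1.47e-06 for unfolded protein response genes, 0.0214 for TGF-beta pathway genes and 0.0451 for fibroblast markers. With an estimated correlation none of these calls held (0.943, 0.24, 0.865 and 0.943), and those for TGF-beta genes and fibroblast markers also ended with slide as a block (0.081 and 0.184). Of 100 splits drawn for the difference of effects, 48 gave at least 4 lists (highest other 13), so chance cannot be excluded for the lists. As the real split gave 0 genes, all 100 gave at least as many by construction, which says nothing about chance (highest other 1327). A split that called 1327 genes where the real one called 0 points to a structure of the samples, whose source was not tested.

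In ATII cells the real counts were 0 genes and 0 lists, so that 35 of 35 splits gave at least as many by construction, which says nothing about chance (highest other 1 gene and 14 lists). For ATII cells against fibroblasts, 1 of 35 splits, the real one, gave as many genes (10081, highest other 2030). Chance can be excluded over these splits, but they ignore slide and replicate number, which vehicle arrays of both cell types share. The split with 2030 genes follows the slide, and with slide as a block the count was 10144. For lists, 5 of 35 splits gave at least 10 (highest other 10), but the 4 others kept 3 of 4 arrays of each cell type together and so held part of the same difference, so this count does not settle whether chance can be excluded. Splits with 2 arrays of each cell type on either side gave at most 7 lists.

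In 22 of 369 groups of 4 arrays, for the 123 genes named in the comparisons, a sample lay far from the other 3. Chance alone gives about 1 in 20 such groups. In ATII cells with BAPN it was replicate 4, the array of that group on slide 2, each time, with levels of −6.27 for Ugt2b37, −6.01 for Fam170a, −7.10 for Exph5, −4.40 for Pnliprp1 and 3.69 for Vat1. In vehicle-treated ATII cells it was replicate 1 for Cd8a (−3.38), Svs5 (−1.80) and Epcam (3.72), and replicate 2 for Ccn5 (−2.22). It was replicate 3 for Tcf21 (−2.13) and Igfbp2 (−0.326), and replicate 4 for Ahsg (−4.41), Oaz3 (−4.61), Col15a1 (−2.18), Ms4a7 (−6.59) and Prl2c5 (−3.11). In vehicle-treated fibroblasts it was replicate 2 for Svs5 (−3.05), Loxl2 (4.48, against 5.96 to 6.08 on the others, and 4.515 on BAPN replicate 2), Pdia4 (1.94) and Nanos1 (−1.49). It was replicate 3 for Cd74 (−3.58) and replicate 4 for Socs6 (−1.03).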

How the results depend on the processing

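Fits of each slide alone, of bright features and with the position correction were chosen after the data had been seen, and the other settings were planned. A single-slide fit leaves 1 BAPN array of fibroblasts (slide 1) or of ATII cells (slide 2), which is assumed to vary like the other groups. Except where a fit tests fewer features or arrays, the cause of a changed value was not tested. Dim features limit these data: 94.28% of bright features had a 95% interval of the fibroblast effect inside 2-fold, against 60.5% of all. The share of all was 89.65% with normexp and quantile scaling and 60.48% with quantile scaling alone, so it depends on the background step. On slide 2 alone, with fewer arrays, the ATII share was 41.36% against 69.7%.

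The fibroblast count of 4193 genes was 2016 with only the groups compared, 304 on slide 1, 6964 on slide 2, 1060 among bright features and 1727 with the position correction, and ranged from 815 to 4226 when single arrays were left out. In the other settings apart from the replicate block it stayed within 1.5 times. The 2 fibroblast lists became 0 with normexp, quantile scaling, the deposited table, an estimated correlation, slide 2 alone and the position correction, 5 on slide 1 and 1 among bright features, and ranged from 1 to 2 without single arrays. In ATII cells the count of 0 genes became 2 with a trend and robust moderation, 14 with array weights, 5266 on slide 2 and 3 among bright features, and stayed from 0 to 0 without single arrays. The 0 lists there became 2 with normexp and with array weights, 1 with quantile scaling, the deposited table, no filter and slide 1, and ranged from 0 to 3 without single arrays.

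For the difference of effects, the 0 genes became 2 with normexp and with no filter, 1930 with array weights, 1 at a threshold of 0.1, 92 on slide 1 and 142 among bright features, and ranged from 0 to 271 without single arrays. Its 4 lists became 2 with normexp, quantile scaling, the deposited table, the mean of probes, slide as a block, slide 2, bright features and the position correction, 0 with an estimated correlation, and ranged from 2 to 6 without single arrays. For ATII cells against fibroblasts, the 10081 genes became 6598 on slide 1, 4626 on slide 2 and 5625 among bright features, with fewer arrays or features, and the 10 lists 3 with an estimated correlation. Without single arrays they ranged from 8646 to 9756 genes and from 9 to 10 lists.

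With the replicate number as a block, the fibroblast comparison had 0 genes and 3 lists, 2 higher and 1 lower. The higher ones were cell cycle and unfolded protein response genes (camera, adjusted p = 0.0153 and 0.00588). The difference of effects had 8 lists, while ATII cells had 1 list. In the BAPN comparisons the numbers did not pair the arrays over all features (r of deviations of same-numbered arrays −0.0839, 0.101 and −0.0436 in fibroblasts and 0.228, −0.147 and −0.153 in ATII cells), and only ATII arrays numbered 1 correlated best with their own number. Single genes did share levels within a number, such as Loxl2 on fibroblast arrays numbered 2 (4.476 and 4.515) and Loxl4 on ATII arrays numbered 1 (0.166 and 0.127). In the comparison of cell types the block gave 9066 genes, 8838 of them among the 10081, the 10 lists still passed, and no call changed among the genes named.

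Signs turned for lysyl oxidase genes and for Cd74, none of which had passed with BAPN. In fibroblasts Lox was −0.056 with quantile scaling and −0.056 with the deposited table, −0.065 with the mean of probes, −0.10 with array weights, −0.04 without vehicle replicate 2, −0.16 without BAPN replicate 1 and −0.10 on slide 2, and Loxl2 was 0.29 without BAPN replicate 2 and 0.045 on slide 1. Without single arrays they ranged from −0.16 to 0.20 and from −0.57 to 0.29. In ATII cells Loxl1 was −0.0077 with quantile scaling, −0.013 with the deposited table, −0.027 with the mean of probes, −0.049 with array weights, −0.042 without vehicle replicate 1, −0.021 without vehicle replicate 3 and −0.089 on slide 2. Loxl2 was −0.027 with the mean of probes and −0.028 without BAPN replicate 4. Loxl3 was −0.0018 with median centring, −0.045 with array weights, −0.0024 and −0.032 without vehicle replicates 1 and 3, and −0.0082 and −0.030 without BAPN replicates 1 and 4. Loxl4 was 0.059 without the replacement array, 0.14 without vehicle replicate 1, 0.028 without BAPN replicate 3, 0.14 on slide 2 and 0.046 with the position correction. Cd74 was −0.22 on slide 2. The highest values without single ATII arrays were 0.082 for Loxl1, 0.19 for Loxl2 and 0.055 for Loxl3, and the lowest was −0.21 for Loxl4. In the difference of effects Loxl4 was −0.0050 with the mean of probes, −0.00092 without fibroblast BAPN replicate 1 and −0.056 without ATII BAPN replicate 1, and Loxl2 was −0.20 without fibroblast BAPN replicate 2. The highest values without single arrays were 0.30 and 0.67.

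Of 861 values for the 34 fibroblast genes, 614 kept direction and call, 237 lost the call, 1 gained it and 9 turned sign. Of 933 values for 35 genes in ATII cells, 890 kept both, 21 gained a call and 22 turned. Of 1077 values for 33 genes in the difference of effects, 1019 kept both, 54 gained a call and 4 turned. Of 1160 values for 44 genes between cell types, 1144 kept both, 13 lost the call, 3 gained it and 0 turned.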

Other observations

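Fibroblast cultures carried transcripts of macrophages. Of the leukocyte genes, chosen after their values were seen, the log2 change of ATII cells over fibroblasts in vehicle was −1.56 for the receptor gene Csf1r, −2.02 for Cd68, −3.48 for the mannose receptor gene Mrc1 and −6.05 for the complement gene C1qa (adjusted p = 3.88e-05, 4.82e-05, 3.73e-05 and 5.45e-07; limma with Benjamini-Hochberg adjustment). The level of Tyrobp in fibroblasts was 2.12 ± 0.61 and that of Ms4a7 0.76 ± 1.07 (SD, n = 4). With BAPN in fibroblasts, Csf1r had a log2 change of −0.11 (adjusted p = 0.781) and Cd68 of 0.29 (adjusted p = 0.54), and the list of these markers had a median of −0.06 (adjusted p = 0.899). Within the ATII cultures the surfactant gene Sftpb was higher than in fibroblasts (5.03, adjusted p = 3.19e-08), while the lipid transporter gene Abca3 had a log2 change of 0.10 that did not pass (adjusted p = 0.74).

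Matrix-degrading and contractile genes differed between the cell types in both directions. Of 29 matrix proteases and inhibitors, 8 were higher and 13 lower in ATII cells (8 and 14 adjusted over the list alone; list adjusted p = 0.868), with the gelatinase gene Mmp9 at least 106-fold higher and the membrane protease gene Mmp15 at least 27.2-fold higher. Of 18 contractile and myofibroblast genes, 2 were higher and 9 lower (3 and 9 adjusted over the list alone; list adjusted p = 0.109), with S100a4 42.0-fold lower (−5.39 ± 0.13, SE) and the integrin gene Itga8 10.3-fold lower (−3.37 ± 0.49).

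The lysosomal list, the position test and the permutations within slides below were chosen after the ATII values had been seen, while the tests on brightness and on other probes were set down before their own results were seen, although the reading of the other-probe value was tightened afterwards. After the high places of Atp6v0a1, Neu1 and Dpp7 were noticed, a list of 82 lysosomal genes was written from background knowledge, and 6 genes seen first were left out of the test. In ATII cells the 74 others that were tested had a median log2 change of 0.21 with BAPN, 66 of them above 0 and 0 past the threshold (camera p = 1.89e-11, and p = 0.0594 with an estimated correlation), and medians of 0.20 on slide 1 and 0.35 on slide 2. In fibroblasts the median was 0.15, with 45 of 74 above 0 (camera p = 0.00232, p = 0.361 with an estimated correlation and p = 0.281 with the position correction). Of the 74, 6 passed the threshold in either direction, against 4193 of all 32255 features tested there. Exact permutation tests gave p = 0.0857 over 35 permutations and p = 0.111 over the 18 within slides, which are too few for a p under 0.05. Camera on the difference between the cell types gave p = 0.302, p = 0.753 with an estimated correlation, p = 0.604 in the other direction on slide 1 alone and p = 0.000207 with the position correction, and no exact permutation test was run on it. The mean over the list differed by 0.23 between the ATII groups, and an exact two-sided permutation test over 70 permutations gave p = 0.0857. Within each slide every ATII BAPN array lay above every vehicle array. An exact two-sided test over the 30 permutations within slides gave p = 0.0667 for a difference of 0.26 with slide as a block. The real grouping already had the largest rise that these levels allow within slides, so this test could not have given a lower p.

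A technical explanation for the ATII value by spot position is argued against by the corrected fit, in which the list median was 0.196, with 67 of 74 above 0. Camera with the preset correlation gave p = 4.41e-14 there. The estimated correlation and the exact permutation tests were run on uncorrected values only. An explanation by brightness is argued against by the place of the list median at percentile 100 of 10000 random lists matched on mean level (highest 0.0954). Of 24 other probes of these genes, 66.7% were above 0, with an exact 95% interval of 44.7% to 84.4% that includes the 50.4% of all tested ATII features. A higher level of lysosomal transcripts under BAPN therefore stays a hypothesis. The estimated correlation and the exact test over all 70 permutations each gave a p above 0.05. The exact test within slides could not have given a p under 0.05 for these levels, so it decides nothing. Differences between the cultures other than the treatment cannot be told apart from an effect of BAPN, since the labels do not say whether replicates were prepared together.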
